A study of Rattus norvegicus with 15 samples.

How the data were processed

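Messenger and other RNA was measured by RNA-seq of total RNA in 15 libraries from rats, 8 of mesenteric artery and 7 of kidney cortex. The groups were 4 wild-type and 4 deletion arteries, and 3 wild-type and 4 deletion kidneys, as the sample titles give them. The titles call every kidney and artery sample male, and number the samples within each group. No label says that each library came from its own animal or ties a kidney to an artery, so the libraries were treated as independent, and errors and p-values describe the spread between these libraries.

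The deposited table holds FPKM values (fragments scaled by the length of the gene and the size of the library), 1 column per library. The submitters' notes name Trim Galore 0.6.2, HISAT2 2.2.1, DESeq2 1.46.0 and the genome build rn7, with no role for each. The tool that made the FPKM values is not given in the sources used here. Counts of reads were not used here and the depth of each library is unknown, so no counting interval or limit of detection is given. The table has 40694 rows, of which 6337 carry no gene identifier and are 0 in all libraries. The 34357 rows with an identifier were kept, each as 1 gene; 1117 of the names occur on more than 1 row. The identifiers are the gene symbols with a prefix, so genes are named by symbol. Coordinates are those of the table, on rn7.

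Values were analysed as log2(FPKM + 0.5) without further scaling. In each tissue, genes with a mean of at least 0.5 FPKM over all libraries of the tissue were tested, deletion against wild-type, with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend and robust moderation). All tests are two-sided. P-values were adjusted by the Benjamini-Hochberg method and a gene was called changed at an adjusted p under 0.05. The difference of the deletion effect between tissues was tested as the interaction of tissue and genotype over all 15 libraries. For Npr3, the difference of the group means in FPKM was also tested by an exact permutation test. On simulated data with the same group sizes, 100 genes with a log2 change of 1 and 100 with a log2 change of 2 were recovered at 61% and 92% in the artery design of 16470 genes, and at 55% and 86% in the kidney design of 15444 genes. Of the calls on simulated data, 2.48% in the artery design and 4.73% in the kidney design were false. Genes were simulated independently of each other, and the changed ones were taken only from genes with a mean log2 value above 1. The simulation held no structure shared between genes, so these rates need not hold for the real libraries.

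A set of 39 gene lists (the neighbours of the deleted interval, pathways, and markers of the cell types that either tissue could hold) was tested with camera, at a preset correlation between genes of 0.01, where at least 5 members were measured. The same lists were tested with camera at an estimated correlation, with fry, and with an exact permutation test of the mean log2 value of the list per library. Calls were also counted among the members of a list, adjusted over the list alone. The genes to be named were Npr3, the neighbours of the interval, called genes in order of effect or, with fewer than 10 called, the 10 genes with the smallest p in each tissue, and the 2 to 4 members with the smallest p of each list called. The groups, tests, lists, rule for named genes and most alternatives were chosen before the data were examined.

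The alternatives were pseudocounts of 0.1 and 1, no filter, a filter at 1 FPKM, median-of-ratios scaling, quantile normalization, moderation without the robust option, limma array weights, the replicate number as a block, 1 fit over both tissues, a fold change of at least 1.5 as a second threshold, windows of 2 Mb and 5 Mb around the interval, leaving out each library in turn, and the mean of the adipocyte list as a covariate. Alternatives chosen after seeing the data were a test of protein-coding genes alone, the mean of the T and NK cell, B cell and macrophage lists as a covariate, and the exact permutation test of the lists. The table of protein-coding genes follows another assembly of the rat genome and was used by name alone. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. A column of the table that gives a coverage value for no stated sample was not used here.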

Results

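RNA was measured in mesenteric artery and kidney cortex of Dahl salt-sensitive rats, an inbred strain whose blood pressure rises on a salty diet. The rats were wild-type or lacked a noncoding interval of 30.4 kb on chromosome 2 (60825801 to 60856216 on rn7), the rat counterpart of a human haplotype region beside the gene of the natriuretic peptide clearance receptor, Npr3. The comparison asks which genes the loss of the interval affects in each tissue. There were 4 wild-type and 4 deletion arteries, and 3 wild-type and 4 deletion kidneys. Read depths are unknown; the FPKM values of a library summed to between 285679 and 433477 in the arteries and between 376270 and 459847 in the kidneys.

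The tissues carried their own markers. Acta2, the smooth muscle actin, stood at 796 FPKM ± 234 (SD, n = 8) in artery and 11 ± 4.04 (SD, n = 7) in kidney. Slc34a1, a phosphate transporter of the proximal tubule, stood at 0.343 ± 0.378 (SD, n = 8) in artery and 1040 ± 111 (SD, n = 7) in kidney. Adipoq, made by fat cells, reached 716 ± 184 FPKM (SD, n = 8) in the arteries, against 2.86 ± 0.672 (SD, n = 7) in the kidneys. Haemoglobin transcripts made up 33% of the summed FPKM in the artery labelled wild-type 4, and between 1.61% and 12% in the other arteries. Rn7sl1, a small cytoplasmic RNA, made up 1.89% to 12.7% of the sum in arteries and 8.23% to 22% in kidneys.

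In the library labelled kidney male wild-type 3, the sex-linked genes went against the label. Xist, which is transcribed from the inactive X chromosome, stood at 81.1 FPKM in this library and between 0.0989 and 1.3 in the other 14 libraries. The Y-linked genes Kdm5d, Eif2s3y, Uty, Ddx3, Sry2 and LOC108353316 were listed at 0 in it, and Eif2s3y lay between 24.1 and 39.6 FPKM in the others. This library also held 172 FPKM of Adh6 and 0.0505 FPKM of the organic anion transporter Slco1a1, against 0.346 to 0.805 and 50 to 133 in the other kidneys. It was kept in the wild-type kidney group, so a kidney difference between genotypes can carry a difference of this library.

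**Figure D1:**
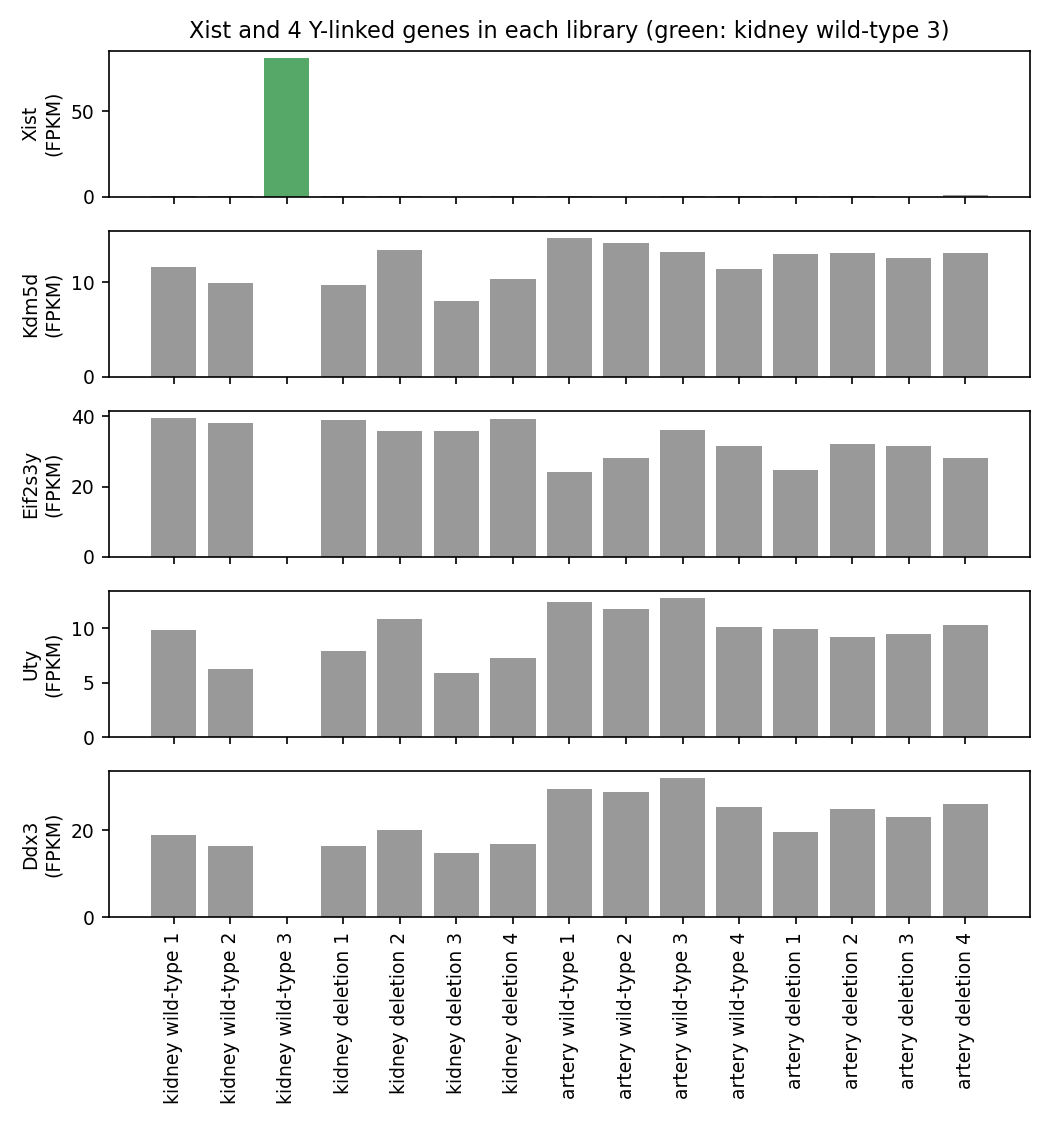
Xist and Y-linked genes in FPKM in each of the 15 libraries, by tissue and genotype. The library labelled kidney male wild-type 3 stands at 81.1 FPKM of Xist, and its Y-linked genes are listed at 0.

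The deleted interval itself holds 1 gene model in the table, LOC108350170 (60847918 to 60848940, plus strand), which was listed at 0 in all 15 libraries. No annotated gene of the interval was therefore measured that could be compared between genotypes, and the genotype labels could not be checked from it. Npr3 lies 9.3 kb from the interval (chromosome 2, 60865483 to 60933432, minus strand). It was higher in artery (28.7 FPKM ± 7.04, SD, n = 8) than in kidney (6.33 ± 2.38, SD, n = 7).

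Npr3, the receptor that clears natriuretic peptides from the circulation, did not pass the test in either tissue. In artery it averaged 25.0 FPKM ± 5.24 (SD, n = 4) in wild-type and 32.4 ± 7.17 (SD, n = 4) in deletion rats. The ratio from the limma fit, made on log2(FPKM + 0.5), was 1.29 (95% confidence interval 0.971 to 1.72). The wild-type arteries held 30.7, 27.8, 19.1 and 22.3 FPKM and the deletion arteries 28.4, 42.6, 26.5 and 32.0 FPKM. The log2 fold change was 0.37 (SE 0.18, limma unadjusted p = 0.0737, adjusted p = 0.893 over all genes). The exact permutation p was 0.143 over 70 arrangements, the smallest possible being 0.0286. Over the alternatives the unadjusted limma p ran from 0.0328 without wild-type 1 to 0.316 with the adipocyte covariate. In kidney Npr3 averaged 6.41 FPKM ± 1.86 (SD, n = 3) in wild-type and 6.27 ± 2.995 (SD, n = 4) in deletion rats. The ratio from the limma fit, which is not the ratio of these FPKM means, was 0.944 (95% confidence interval 0.598 to 1.49). The difference of the FPKM means was -0.135 (exact permutation p = 0.971 over 35 arrangements). The deletion kidneys held 5.05, 10.7, 4.39 and 4.91 FPKM, and the wild-type kidneys 8.52, 5.01 and 5.69. The effect in artery exceeded that in kidney by 0.45 on the log2 scale (SE 0.37, limma adjusted p = 0.947 for the difference). This difference was 0.72 without kidney deletion 2, 0.24 without kidney wild-type 1 and 0.26 with array weights. The artery value was 0.22 with the adipocyte list as a covariate and 0.23 without deletion 2; the kidney value of -0.08 was -0.36 without deletion 2, -0.23 without wild-type 2, -0.15 without wild-type 3, 0.13 without wild-type 1, 0.04 without deletion 3, -0.02 without deletion 1, -0.00413 without deletion 4 and 0.01 with array weights.

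**Figure D2:**
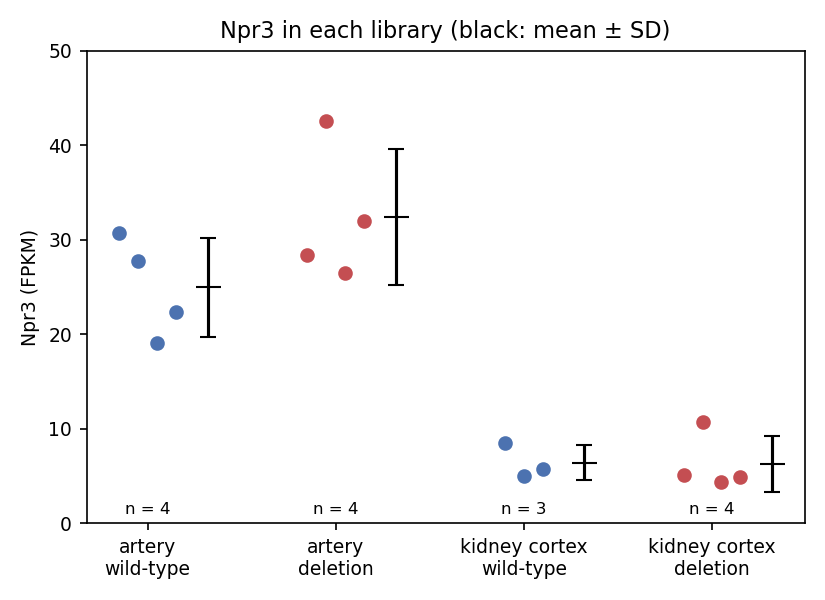
Npr3 in FPKM in each library of each tissue and genotype, with group means and SD. The deletion arteries reach from 26.5 to 42.6 and overlap the wild-type arteries, and 1 deletion kidney stands at 10.7.

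The other genes around the interval did not pass either. Of 23 listed neighbours, 18 were measured in artery and 19 in kidney, and limma called 0 in each tissue, both adjusted over the list alone and over all genes, with 0 at an unadjusted p under 0.05. In artery the log2 fold changes ran from -0.23 for Golph3, a Golgi protein, to 0.37 for Npr3. Golph3 stood at -0.36 without deletion 3. In kidney they ran from -0.42 for Amacr, a peroxisomal racemase of branched-chain fatty acids, to 0.84 for Prlr, the prolactin receptor. Prlr averaged 30.8 FPKM ± 17.0 (SD, n = 3) in wild-type and 50.7 ± 16.3 (SD, n = 4) in deletion kidneys, and its value was 0.27 without wild-type 3. Amacr stood at 209 FPKM in wild-type 3 and at 117 and 109 in the other wild-type kidneys. Its value was -0.12 without wild-type 3 and 0.01 with array weights. Sub1, a transcription coactivator and the next measured gene beyond Npr3, had log2 fold changes of 0.15 (SE 0.20) in artery and -0.14 (SE 0.15) in kidney. The artery value was -0.04 without wild-type 1, 0.30 without wild-type 3, 0.23 without deletion 1 and 0.07 without deletion 2. The kidney value was -0.22 without wild-type 1, -0.07 without wild-type 2 and -0.08 without deletion 2. The RNA-processing enzyme Drosha had 0.25 (SE 0.14) in kidney. With array weights its value was 0.37 and it alone was called, at an adjusted p of 0.0245 over the list alone. Within 2 Mb of the interval limma called 0 of 20 genes in artery and 0 of 21 in kidney, with 0 and 1 at an unadjusted p under 0.05. Within 5 Mb it called 0 of 37 in each tissue, with 0 and 1 unadjusted.

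**Figure D3:**
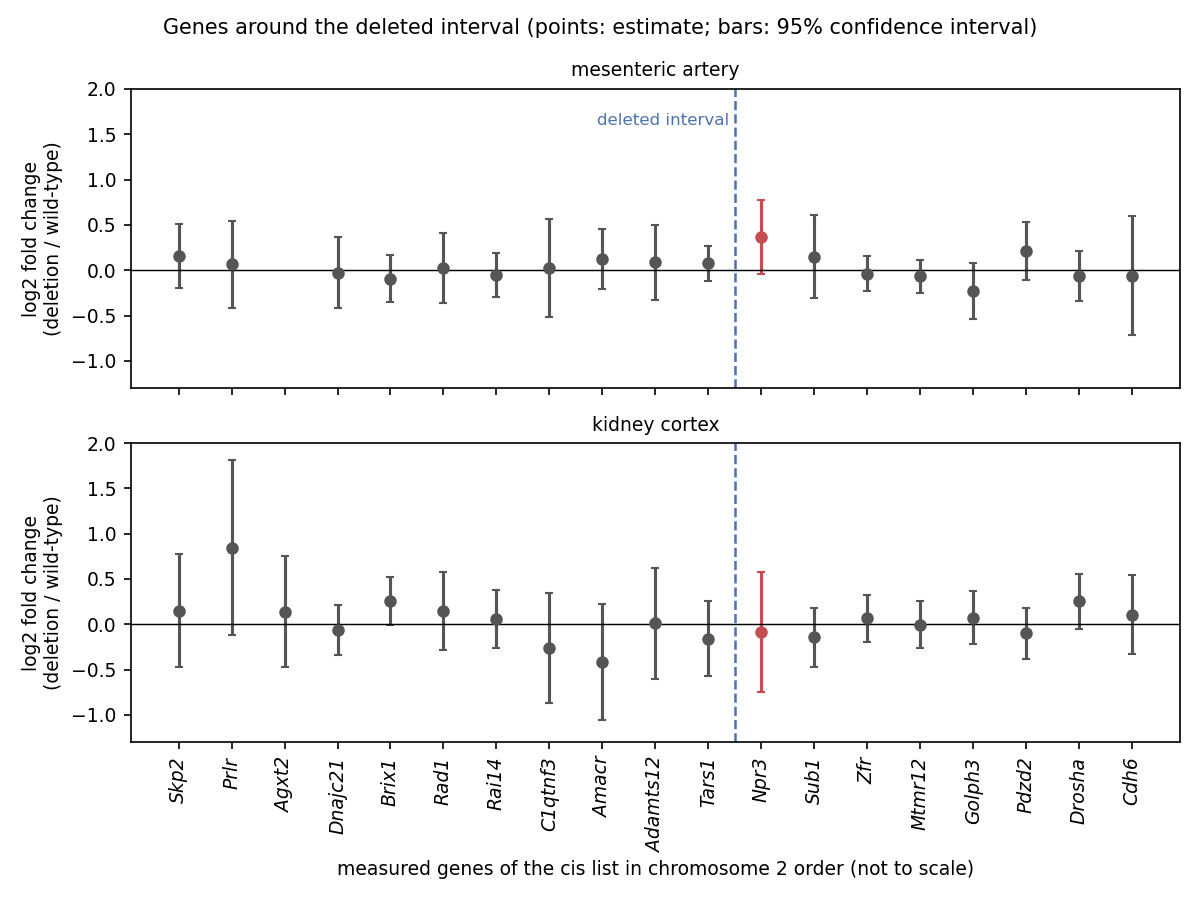
Log2 fold change, deletion over wild-type, of the measured neighbours of the deleted interval in artery and kidney, by gene; bars are 95% confidence intervals. The values lie between -0.42 and 0.84, and each interval includes 0.

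In the arteries no single gene passed the threshold. Closest to it was LOC120094666, an uncharacterised gene on chromosome 9 (38491054 to 38491752, minus strand), at 2.46, 1.31, 4.04 and 3.45 FPKM in the wild-type arteries and listed at 0 in all 4 deletion arteries (limma adjusted p = 0.051). In the kidneys this gene was above 0 in wild-type 2 (1.12 FPKM), deletion 1 (0.591 FPKM) and deletion 2. It was listed at 0 in wild-type 1, wild-type 3, deletion 3 and deletion 4. Its absence from the deletion arteries therefore did not extend to all deletion kidneys. Among the 10 genes with the smallest p, which are named here as not passing, Phgdh, the first enzyme of serine synthesis, averaged 21.3 FPKM ± 1.87 (SD, n = 4) in wild-type and 30.8 ± 2.64 (SD, n = 4) in deletion arteries. Scarb1, the receptor for high-density lipoprotein, averaged 23.5 ± 0.570 and 30.7 ± 0.968 FPKM (SD, n = 4 each), and Mrps28, a protein of the mitochondrial ribosome, 7.84 ± 0.271 and 11.2 ± 0.676 (SD, n = 4 each). Fxyd5, a regulator of the sodium pump, averaged 10.7 ± 0.873 and 7.19 ± 0.940 FPKM (SD, n = 4 each). The remaining 5 were Plekhh3 with a log2 fold change of 0.51, LOC687780 with 1.25, LOC120103189 with 0.85, Mir511 with -1.14 and the natural killer cell receptor gene Ly49si3 with -1.08; these and the 4 genes above had an adjusted p of 0.893. With a pseudocount of 1 and of 0.1, Ly49si3 had -0.77 and -1.63 and Mir511 -0.82 and -1.70.

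Of 16470 genes tested in artery, limma called 0, with 863 at an unadjusted p under 0.05 (613 higher and 250 lower in deletion rats) where chance gives 824. The median log2 fold change over all these genes was 0.0436, so the values as a whole lean to higher. With median-of-ratios scaling this median was 0.000387, with 758 genes at an unadjusted p under 0.05. The groups did not overlap in 535 genes, or 3.25%, against 2.86% by chance. The count became 1 with a pseudocount of 0.1, with the immune marker covariate and without wild-type 2, each time LOC120094666, at adjusted p of 0.00863, 0.0233 and 0.0053, and without deletion 3, where LOC120096562 passed at 0.000987; the adjusted p of LOC120094666 ranged up to 0.443 over the alternatives.

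Genes of the interferon response, the antiviral programme, were called lower as a list in the deletion arteries. Camera at the preset correlation gave an adjusted p of 3.25e-13, with a median log2 fold change of -0.53 and 18 of 19 members lower (adjusted p = 0.47 with an estimated correlation). Limma called 5 members adjusted over the list alone (Mx2, Rig1, Ifih1, Usp18 and Ifit2) and 0 over all genes. Mx2, an antiviral GTPase, averaged 24.3 FPKM ± 9.43 (SD, n = 4) in wild-type and 12.4 ± 0.635 (SD, n = 4) in deletion arteries, and Usp18, a brake on interferon signalling, 10.7 ± 4.02 and 5.46 ± 1.17 (SD, n = 4 each). The RNA sensors Rig1 (also called Ddx58) and Ifih1 averaged 14.1 ± 3.01 and 9.63 ± 1.77 FPKM in wild-type, and 9.61 ± 0.737 and 6.76 ± 0.710 in deletion arteries (SD, n = 4 each). The mean log2 value of the list was 4.48 in wild-type 4, between 3.39 and 3.87 in the other wild-type arteries, and between 3.25 and 3.55 in the deletion arteries. Without wild-type 4, the library with 33% haemoglobin, the median was -0.36, and the list was still called.

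Camera called lists of energy metabolism higher in the deletion arteries. For oxidative phosphorylation 33 of 36 members were higher, with a median log2 fold change of 0.24 and a camera adjusted p of 5.85e-11 (adjusted p = 0.48 with an estimated correlation). Its members with the smallest p were Ndufv1 of complex I, at 24.4 FPKM ± 2.50 in wild-type and 32.0 ± 3.19 in deletion arteries, Cox5a of complex IV, at 26.3 ± 2.15 and 35.3 ± 5.10 (SD, n = 4 each), Sdhc and Uqcrc1. For hypoxia and glycolysis 17 of 20 members were higher, with a median of 0.25 and an adjusted p of 0.000121 (adjusted p = 0.15 with an estimated correlation). Fry also called this list, at an adjusted p of 0.013. Lactate dehydrogenase Ldha averaged 142 FPKM ± 15.9 in wild-type and 186 ± 14.3 in deletion arteries, and Tpi1, a glycolytic isomerase, 63.7 ± 1.26 and 84.1 ± 14.7 (SD, n = 4 each); the members with the next smallest p were Gapdh and Hk2.

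Camera also called lists of fat cells and lipid metabolism higher. For adipocyte markers 19 of 20 members were higher, with a median of 0.23 and a camera adjusted p of 0.00211 (adjusted p = 0.69 with an estimated correlation). Fatty acid synthase Fasn averaged 290 FPKM ± 168 in wild-type and 581 ± 212 in deletion arteries, the insulin-responsive glucose transporter Slc2a4 21.0 ± 4.46 and 33.9 ± 7.08, and the triglyceride enzyme Dgat2 230.5 ± 53.8 and 331 ± 59.6 (SD, n = 4 each). Fatty acid oxidation had a median of 0.13, led by Acads and Acadm, and cholesterol biosynthesis a median of 0.14, led by Fdft1 and Lss; both had an adjusted p of 0.00938 (adjusted p = 0.74 and 0.69 with an estimated correlation). These calls depended on single libraries. Without wild-type 2 the adjusted p were 0.0627 for adipocyte markers, 0.286 for fatty acid oxidation and 0.166 for cholesterol biosynthesis. Without deletion 2 they were 0.229 for adipocyte markers and 0.217 for fatty acid oxidation, and without deletion 3 they were 0.0635 and 0.419; for cholesterol biosynthesis the adjusted p was 0.0611 without wild-type 1 and 0.339 without deletion 1. Leaving out single libraries, the medians ran from 0.09 (without deletion 2) to 0.37 (without deletion 4) for adipocyte markers, from 0.06 (without deletion 3) to 0.19 (without deletion 4) for fatty acid oxidation, and from 0.08 (without deletion 1) to 0.23 (without wild-type 3) for cholesterol biosynthesis. With the adipocyte list as a covariate the median of fatty acid oxidation was -0.03, and with array weights the adjusted p were 0.0964 for adipocyte markers and 0.165 for fatty acid oxidation.

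Of the lists of blood and immune cells, camera called 5 lower in the deletion arteries, while B cell and plasma cell markers (median -0.14, mean 0.02, adjusted p = 0.258) and MHC genes (median -0.13, adjusted p = 0.155) were not called. T and NK cell markers had a median of -0.45, with 16 of 16 members lower (adjusted p = 0.000185, and adjusted p = 0.69 with an estimated correlation); Cd2 averaged 2.88 FPKM ± 2.28 in wild-type and 1.25 ± 0.485 in deletion arteries (SD, n = 4 each), and Cd4 21.2 ± 8.37 and 16.0 ± 5.40 (SD, n = 4 each). Neutrophil and mast cell markers had a median of -0.71, with the mast cell genes Cma1 and Ms4a2 first (adjusted p = 0.000795, and adjusted p = 0.58 with an estimated correlation). Macrophage markers had a median of -0.18, with Ccr2 and Msr1 first (adjusted p = 0.00211, and adjusted p = 0.69 with an estimated correlation). Cytokines, chemokines and adhesion molecules had a median of -0.26, with Nfkbia and Cxcl10 first (adjusted p = 0.00092, and adjusted p = 0.47 with an estimated correlation). Erythrocyte markers had a median of -0.84, with Hbq1b and Ahsp first (adjusted p = 0.00772, and adjusted p = 0.72 with an estimated correlation). Wild-type 3 and deletion 2 had mean log2 values of 4.03 and 3.43 for B cell markers, against 0.776 to 2.07 in the other arteries. Without wild-type 3 the adjusted p was 0.131 for T and NK cells, 0.0609 for neutrophils and mast cells and 0.506 for macrophages. Leaving out single libraries, the medians ran from -0.90 (without wild-type 1) to -0.12 (without wild-type 3) for T and NK cells and from -0.40 (without deletion 3) to -0.07 (without wild-type 3) for macrophages. Without wild-type 3 they were -0.37 for neutrophils and mast cells, -0.11 for cytokines and -1.60 for erythrocyte markers. For erythrocyte markers the median was 0.06 without wild-type 4 (adjusted p = 0.867) and -0.39 without deletion 1 (adjusted p = 0.146); the adjusted p was 0.0609 with quantile normalization and 0.122 with the adipocyte covariate.

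The other lists that camera called lower in artery were immediate early genes, proximal tubule markers, sex-linked genes, and vasoactive receptors and ligands. Immediate early genes, which respond within minutes to stimulation, had a median of -0.22, with 19 of 25 members lower (adjusted p = 0.000113, and adjusted p = 0.52 with an estimated correlation); the flow-responsive factor Klf2 averaged 41.5 FPKM ± 3.56 in wild-type and 30.3 ± 7.26 in deletion arteries (SD, n = 4 each), and Zfp36, which destabilises messenger RNA, 16.4 ± 1.47 and 13.1 ± 1.66 (SD, n = 4 each). Proximal tubule markers, led by Kap and Ass1, had a median of -0.49 at low levels, Kap averaging 2.15 FPKM ± 1.997 and 0.412 ± 0.543 (SD, n = 4 each; list adjusted p = 0.000624, and adjusted p = 0.47 with an estimated correlation). Sex-linked genes had a median of -0.12, with Uty and Kdm6a first (adjusted p = 0.00938, and adjusted p = 0.47 with an estimated correlation). Vasoactive receptors and ligands had a median of -0.04 (adjusted p = 0.0299, and adjusted p = 0.69 with an estimated correlation), with members on both sides: the cyclooxygenase Ptgs2 averaged 10.4 FPKM ± 3.70 in wild-type and 5.28 ± 2.06 in deletion arteries (SD, n = 4 each), and the adrenergic receptor Adra1d 2.17 ± 0.462 and 3.32 ± 0.235 (SD, n = 4 each). Wild-type 1 also held transcripts of intestinal epithelium: Vil1 stood at 5.91 FPKM, Fabp2 at 14.7 and Epcam at 4.43, against 0.624, 1.33 and 0.469 or less in the other arteries. The transporters Slc5a1 and Slc6a19, which the intestine makes as well as the proximal tubule, stood at 4.01 and 5.03, against 0.717 and 0.458 or less. Kap did not follow these transcripts. It stood at 3.75 FPKM in wild-type 1 and 4 in wild-type 2, where Vil1 was 0.234, and at 0.515 and 0.337 in wild-type 3 and wild-type 4. The median of proximal tubule markers was -0.20 without wild-type 1 and -0.19 without a filter, and the list was still called in both. For sex-linked genes the median was -0.07 without wild-type 2 and the adjusted p was 0.0609 without wild-type 3, 0.0868 without a filter and 0.131 in the fit over both tissues. For vasoactive receptors and ligands it was 0.0665 without wild-type 1, 0.0636 without wild-type 2, 0.0631 without wild-type 4, 0.15 without deletion 1, 0.229 without deletion 2, 0.0977 without a filter, 0.056 with quantile normalization and 0.186 with the adipocyte covariate, and the median ran from -0.11 (without wild-type 4) to -0.00341 (without deletion 2).

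In all, camera called 15 of 39 lists in artery, 5 higher and 10 lower. With an estimated correlation it called 0 (smallest adjusted p = 0.15), fry called 1, and the exact permutation test of list means called 0 (smallest adjusted p = 0.78). The exact test could hardly call any list, since its smallest possible unadjusted p is 0.0286, which hypoxia and glycolysis reached. Outside the interferon list, 0 list members were called adjusted over the list alone. The smooth muscle contractile apparatus had a median of 0.13, and natriuretic peptide and cGMP signalling, the pathway of Npr3, a median of 0.08; neither was called. The 24 lists not called had medians between -0.22, for pancreas and intestine markers, and 0.77, for mesothelial markers, and adjusted p from 0.107 to 0.948. For lymphatic endothelial, endothelial, collecting duct, cis neighbour, cell cycle and collagen lists the median was above 0 and the test pointed down, and for the B cell, glomerular and striated muscle lists the mean was above 0 and the median and the test were below. Camera at the preset correlation called the smooth muscle list higher without wild-type 2 (adjusted p = 0.0327), without deletion 2 (adjusted p = 0.0256) and with the adipocyte covariate (adjusted p = 0.000458). With an estimated correlation the adjusted p of this list was 0.86 over all libraries. Its median was -0.04 without wild-type 3, and that of the natriuretic peptide list was -0.04 without wild-type 3.

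**Figure D4:**
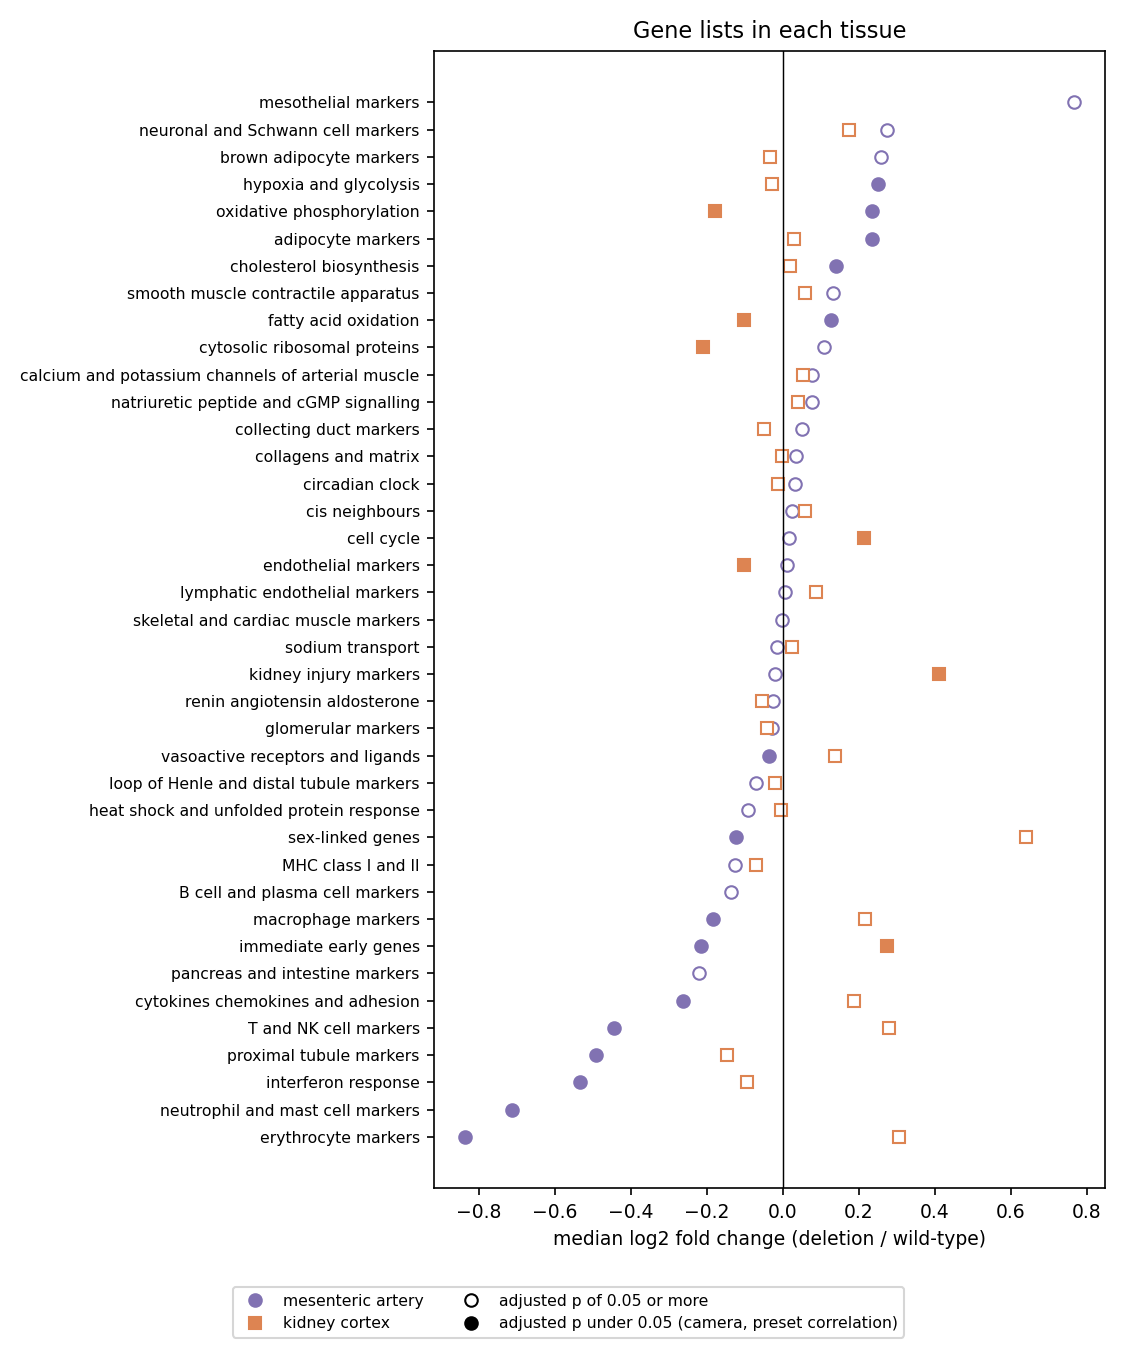
Median log2 fold change, deletion over wild-type, of each gene list in artery (circles) and kidney (squares); filled symbols have a camera adjusted p under 0.05 at the preset correlation. Erythrocyte markers stand lowest in artery at -0.84, and injury markers at 0.41 in kidney.

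In the kidneys no single gene passed the threshold. Among the 10 genes with the smallest p, named here as not passing, the stress-induced Gadd45g averaged 13.9 FPKM ± 5.16 (SD, n = 3) in wild-type and 27.8 ± 6.19 (SD, n = 4) in deletion kidneys. Car3, a carbonic anhydrase, averaged 0.273 ± 0.232 (SD, n = 3) and 1.06 ± 0.283 (SD, n = 4). These are trace levels, against 960 to 2190 FPKM in the arteries. The log2 fold change of Car3 in kidney was 1.04, and ran from 0.494 to 1.78 over the alternatives. Fxyd4, a regulator of the sodium pump in the collecting duct, averaged 12.2 ± 1.84 (SD, n = 3) and 7.65 ± 1.89 (SD, n = 4), and the nucleolar protein Nol12 5.05 ± 0.2001 (SD, n = 3) and 3.39 ± 0.182 (SD, n = 4). The remaining 6 were noncoding or uncharacterised: LOC120093316 had a log2 fold change of 1.37, LOC120100461 1.07, LOC120093965 1.02, Snord41 1.30, LOC120103572 -0.99 (-0.64 without wild-type 3) and Mir374b -1.27. With a pseudocount of 1 and of 0.1, LOC120093316 had 0.89 and 2.63 and Snord41 0.84 and 2.66.

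Of 15444 genes tested in kidney, limma called 0, with 217 at an unadjusted p under 0.05 (145 higher and 72 lower in deletion rats) where chance gives 772. The smallest adjusted p was 0.999. The median log2 fold change over all these genes was 0.0437, and -0.00926 with median-of-ratios scaling. The groups did not overlap in 394 genes, or 2.55%, against 5.71% by chance. With array weights 282 genes were called, 188 higher and 94 lower, among them 7 of the 10 above; that fit gave wild-type 2 a weight of 18.2 and the other kidneys 0.268 to 1.86. The fit over both tissues called 1 gene, LOC120093316 (adjusted p = 0.0244), and 1 gene was called without wild-type 1, LOC120095881 (adjusted p = 1.12e-05); without wild-type 3, whose sex-linked genes go against its label, the count was 0 of 15548, with 157 unadjusted.

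Kidney injury markers, genes that tubules switch on when damaged, were called higher as a list in the deletion group. The difference lay mostly in 2 of the 4 deletion kidneys. Camera at the preset correlation gave an adjusted p of 3e-06, with a median of 0.41 and 14 of 16 members higher (adjusted p = 0.98 with an estimated correlation). The hyaluronan receptor Cd44 averaged 3.57 FPKM ± 1.34 (SD, n = 3) in wild-type and 7.41 ± 2.59 (SD, n = 4) in deletion kidneys, and the injury protein Lcn2 1.96 ± 0.586 (SD, n = 3) and 5.25 ± 3.40 (SD, n = 4). Timp1, an inhibitor of matrix proteases, averaged 2.32 ± 0.887 (SD, n = 3) and 3.87 ± 1.10 (SD, n = 4), and Gpnmb 1.70 ± 0.468 (SD, n = 3) and 3.61 ± 1.75 (SD, n = 4). The mean log2 value of the list was 3.50 and 3.36 in deletion 1 and deletion 2, and 2.499 and 2.74 in deletion 3 and deletion 4, against 2.34 to 2.72 in the wild-type kidneys. Lcn2 stood at 7.29 and 8.95 FPKM in deletion 1 and deletion 2 and at 2.02 and 2.72 in deletion 3 and deletion 4. Macrophage markers had mean log2 values of 2.05 and 2.19 in deletion 1 and deletion 2 and 1.44 to 1.98 in the other kidneys. T and NK cell markers had 0.752 and 0.76, against 0.216 to 0.686. Deletion 2 also had the highest share of Rn7sl1 (22%) and the lowest mean of proximal tubule markers among the kidneys (7.37). Without wild-type 1 the median was 0.30 and the adjusted p 0.148; without wild-type 3 it was 0.57 and without deletion 1 it was 0.19, and the list was still called. Camera also called immediate early genes higher, with a median of 0.28 and Egr1 and Ier3 first, and cell cycle genes, with a median of 0.22 and Nusap1 and Ccnb2 first (adjusted p = 0.00309 and 0.00252; for both, adjusted p = 0.98 with an estimated correlation). Cell cycle genes had an adjusted p of 0.0693 without wild-type 1, and a median of 0.37 without wild-type 2, -0.01 without wild-type 3 and -0.05 with array weights. Immediate early genes had an adjusted p of 0.336 without wild-type 1, 0.0644 without deletion 2 and 0.995 with array weights. Their median was 0.14 without wild-type 3 or deletion 2, 0.18 without deletion 1 and 0.02 with array weights.

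Camera called the lists of cytosolic ribosomal proteins, oxidative phosphorylation, fatty acid oxidation and endothelial markers lower in the deletion kidneys. Ribosomal proteins had a median of -0.21, with 29 of 30 members lower (adjusted p = 1.45e-06, and adjusted p = 0.98 with an estimated correlation), Rps20 averaging 392 FPKM ± 188 (SD, n = 3) in wild-type and 250.2 ± 44.2 (SD, n = 4) in deletion kidneys; Rpl32, the member with the smallest p, was the 1 member that was higher. Oxidative phosphorylation had a median of -0.18, with 33 of 36 members lower (adjusted p = 2.52e-06, and adjusted p = 0.98 with an estimated correlation), Atp5f1d averaging 190.1 ± 34.1 (SD, n = 3) and 152 ± 29.0 (SD, n = 4), and Ndufs3 89.6 ± 17.9 (SD, n = 3) and 73.4 ± 11.04 (SD, n = 4). Fatty acid oxidation had a median of -0.10, with Acaa2 and Cyp4a1 first (adjusted p = 0.00071), and endothelial markers a median of -0.10, with Plvap and Cldn5 first (adjusted p = 0.00741; for both, adjusted p = 0.98 with an estimated correlation). Without wild-type 3 the adjusted p of the ribosomal and oxidative phosphorylation lists was 0.844 for each, with medians of -0.07 and -0.01. Without wild-type 1 these medians were -0.35 and -0.37. Deletion 2 had the lowest mean log2 value for oxidative phosphorylation among the deletion kidneys, 6.67 against 7.18 or more. It held 22% Rn7sl1 and had the lowest mean of proximal tubule markers among all kidneys, 7.37 against 7.945 or more. Without deletion 2 the median of oxidative phosphorylation was -0.05 (adjusted p = 0.447) and that of fatty acid oxidation 0.01 (adjusted p = 0.924). Fatty acid oxidation had an adjusted p of 0.0656 without wild-type 1 and a median of 0.02 with array weights, and endothelial markers had an adjusted p of 0.336 without wild-type 1, 0.076 without deletion 1 and 0.0682 without deletion 3, and medians from -0.22 (without deletion 2) to 0.01 (without wild-type 1). With quantile normalization the adjusted p was 0.0579 for the ribosomal list, 0.0875 for oxidative phosphorylation and 0.113 for fatty acid oxidation.

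In all, camera called 7 of 34 lists in kidney, 3 higher and 4 lower; with an estimated correlation it called 0, fry called 0, and the exact permutation test of list means called 0 (smallest unadjusted p = 0.171). The number called was 3 without wild-type 1, 11 without deletion 1, 11 with median-of-ratios scaling and 4 with quantile normalization. In each list 0 members were called adjusted over the list alone. The sodium transport list had a median of 0.02, the renin, angiotensin and aldosterone list -0.05, and natriuretic peptide and cGMP signalling 0.04; none was called, and the last was -0.02 with median-of-ratios scaling, -0.03 with quantile normalization or without wild-type 2, -0.08 without wild-type 3, -0.12 without deletion 2 and -0.02 without deletion 4. The 27 lists not called had medians between -0.15, for proximal tubule markers, and 0.64, for the sex-linked list, which holds the genes that stand apart in wild-type 3. The median was above 0 and the test pointed down for adipocyte, sodium transport and natriuretic peptide lists; the median was below 0 for heat shock, collagen and renin lists, whose mean was above 0, and the test pointed up for the collagen list alone.

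The comparison of the deletion effect between tissues asked whether arteries and kidneys responded differently. Limma called 0 of 17842 genes, with 768 at an unadjusted p under 0.05 (438 higher and 330 lower in artery) where chance gives 892; the smallest adjusted p was 0.947. Camera called 14 of 39 lists, 5 with a higher effect in artery and 9 with a lower one. The effect on oxidative phosphorylation was higher in artery than in kidney by a median of 0.46 (adjusted p = 1.86e-11), with 34 of 36 members in that direction, and that on ribosomal proteins by 0.33 (adjusted p = 7.61e-05; for both, adjusted p = 0.75 with an estimated correlation). The effect on interferon genes was lower by -0.42 (adjusted p = 0.00226), on immediate early genes by -0.40 (adjusted p = 6.74e-06) and on kidney injury markers by -0.40 (adjusted p = 0.000607). For these 3 lists, adjusted p = 0.75 with an estimated correlation. For oxidative phosphorylation and ribosomal proteins the kidney part of the difference rests on single libraries. Without kidney wild-type 3 the kidney medians were -0.01 for oxidative phosphorylation and -0.07 for ribosomal proteins (camera adjusted p = 0.844 for each). The kidney injury difference lay mostly in deletion 1 and deletion 2 of the kidneys. The effect on hypoxia and glycolysis was higher by 0.27 (adjusted p = 0.000607, and adjusted p = 0.058 with an estimated correlation), and fry also called this list at an adjusted p of 0.04. With an estimated correlation 0 lists were called, with array weights 8, and in each list 0 members were called adjusted over the list alone. The median and the test differed in sign for collecting duct, glomerular and MHC lists, none of them called.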

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

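Of the tests below, those of the interferon, oxidative phosphorylation and sex-linked patterns, the splits for the counts at an adjusted p under 0.05 (with array weights too) and for the lists that differ between tissues were chosen only after the result was seen.

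Interferon genes were lower in the deletion arteries, by -0.511 (SE 0.233) in the mean log2 value of the list. Of the 35 splits of the 8 arteries 3, the real one included, gave a difference as large (highest other 0.591), so chance cannot be excluded. With immune cell markers as a covariate 0.942 of the difference was left (-0.481, SE 0.24), and without wild-type 4, 0.623 of it (-0.318, SE 0.155). Camera at the preset correlation still called the list in both, at adjusted p of 2.61e-11 and 5.14e-08, but it does not call it with an estimated correlation (adjusted p = 0.47 as reported). The remainders lie about 2 SE from 0, too close to decide whether fewer immune cells, or that library alone, were the whole cause. The immune list mean ran from 1.56 to 3.65 in wild-type and from 1.43 to 2.83 in deletion arteries. That covariate overlaps between the groups and could remove little of the difference. Each may account for a part, and an effect of the deletion stays open.

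Oxidative phosphorylation genes were higher in the deletion arteries, by 0.231 (SE 0.0857) in the mean log2 value. Of the 35 splits 2, the real one included, gave a difference as large (highest other 0.237), so chance cannot be excluded. Scaling is argued against as the whole cause only by the part that it removed. Median-of-ratios scaling removed 0.209 of the difference (0.0482, SE 0.0305) and quantile normalization 0.177 (0.0409, SE 0.0424). Median-of-ratios scaling left 0.791 (0.183, SE 0.103), which is less than 2 SE from 0, so the remainder itself cannot decide. Camera at the preset correlation still called the list, at adjusted p of 5.74e-09 and 3.4e-11. With adipocyte markers as a covariate 0.607 was left (0.14, SE 0.0825; camera adjusted p = 0.00326), less than 2 SE from 0. Fat around the vessel may therefore account for all or a part of the difference and scaling for a part, an effect of the deletion stays open, and camera does not call the list with an estimated correlation (adjusted p = 0.48 as reported).

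In the library labelled kidney male wild-type 3, 6 of 6 Y-linked genes lay under 5% of their mean in the other kidneys. Low depth or scaling is argued against, since 0.13% of 11546 autosomal genes of like level did so. Of the other 14 libraries 0 lacked these genes, which says nothing on an exchange within the set, since all 15 carry the label male. Xist at 81.1 FPKM with these genes at 0 is the pattern of a female. A female rat under a male label, or an exchange with a female sample outside this set, may be the source, and which of these it was is open.

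For a group of 4 libraries, a library was taken to stand apart where its gap to the nearest other, as a part of the whole range, exceeded Dixon's 95% critical value. This held in 19 of 209 groups, where chance flags about 1 in 20, or 10.5. The wild-type kidneys, with 3 libraries and wild-type 3 among them, were not screened. In the deletion kidneys, kidney 2 stood highest for Npr3 (gap 0.849 of the range), LOC120093965 (0.882) and loop of Henle and distal tubule markers (0.83), and lowest for Tars1 (0.835), Agxt2 (0.914), oxidative phosphorylation (0.835) and fatty acid oxidation (0.84). Kidney 1 stood highest for LOC120093316 (0.933) and kidney 3 lowest for brown adipocyte markers (0.954). In the wild-type arteries, artery 1 stood highest for C1qtnf3 (0.83), artery 2 for endothelial markers (0.908), heat shock genes (0.862) and the share of Rn7sl1 (0.834, at 8.03%), and artery 3 for cell cycle genes (0.839). Artery 3 stood lowest for kidney injury markers (0.872) and artery 4 lowest for Skp2 (0.844) and highest for the summed FPKM (0.859, at 433000 against 312000 or less). In the deletion arteries, artery 4 stood lowest for Tars1 (0.852) and highest for immediate early genes (0.86).

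Between tissues, camera called a different deletion effect for 14 lists, each given here as the median difference in log2 fold change, artery minus kidney. It was above 0 for oxidative phosphorylation (0.464), ribosomal proteins (0.327), adipocyte markers (0.301), hypoxia and glycolysis (0.271) and fatty acid oxidation (0.27). It was below 0 for vasoactive receptors and ligands (-0.16), cytokines (-0.356), immediate early genes (-0.4), kidney injury markers (-0.403), macrophages (-0.403), interferon genes (-0.424), T and NK cells (-0.695), neutrophils and mast cells (-0.771) and erythrocytes (-1.21). With an estimated correlation 0 of these were called, and 37 of 100 splits of the libraries within their tissues, the real one included, gave as many lists (highest other 24), so chance cannot be excluded.

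For the counts of lists and of genes at an unadjusted p under 0.05, chance cannot be excluded either; each number of splits includes the real one. In artery, 12 of 35 splits called as many lists as the real 15 (highest other 23), and 14 gave as many genes at an unadjusted p under 0.05 as the real 863 (highest other 2847). In kidney, 33 of 35 splits called as many lists as the real 7 (highest other 17), and 28 gave as many unadjusted genes as the real 217 (highest other 4038). At an adjusted p under 0.05 the real count is 0, which all 35 splits in each tissue reach by construction, so that this count tests nothing; the highest other split gave 7 genes in artery and 1 in kidney. For the tissue difference 49 of 100 splits gave as many unadjusted genes as the real 768 (highest other 3219). With array weights 11 of 35 splits of the kidneys called as many genes as the real 282, and the highest other called 5031. Splits that call several times the real count point to a structure of the samples: in kidney the highest parted wild-type 1, deletion 1 and deletion 2 from the others, with array weights wild-type 1, wild-type 3 and deletion 2, and in artery wild-type 3, wild-type 4, deletion 2 and deletion 3 from the others.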

How the results depend on the processing

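The tests of protein-coding genes alone, of the immune covariate and the exact test of list means were chosen only after the results were seen. Of 215 values of the main results under the alternatives, 194 were kept, 8 lost calls, 10 gained them and 3 turned. Most of these values are counts, taken as kept within 1.5-fold of the reported count, so the calls behind them could differ. A reported count of 0 was kept only by 0, which the second threshold on fold change gives by construction. Values of Npr3, other single genes and lists were kept where they stayed in direction and on their side of the threshold. Of 1052 values of single genes 985 were kept, 11 gained a call and 56 turned. Of 519 values of gene lists 453 were kept, 42 lost the call, 3 gained it and 21 turned. Npr3 in artery stayed between 0.22 and 0.47 and uncalled in all 21 alternatives, and the tissue difference gave 0 genes in all 25. The interferon, oxidative phosphorylation, hypoxia and glycolysis, immediate early, proximal tubule and cytokine lists in artery kept their call in all 21 fits at the preset correlation. Depth limits the low values by an unknown amount, since no read numbers were used.

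The count of artery genes was 1 with a pseudocount of 0.1 and 1 with the immune covariate, and 0 to 1 leaving out single libraries. Lists called in artery were 0 with an estimated correlation and 0 by exact permutation; in kidney 11 with median-of-ratios scaling, 4 with quantile normalization, 0 with an estimated correlation, 0 by exact permutation and 3 to 11 leaving out single libraries; for the tissue difference 8 with array weights and 0 with an estimated correlation. The count of kidney genes was 282 with array weights, 1 in the fit over both tissues and 0 to 1 leaving out single libraries. With array weights 1 kidney gene near the interval was called, and the kidney value of Npr3 was 0.0142; leaving out single libraries it ran from -0.356 to 0.126. An estimated correlation above the preset one widens the error of a list by construction, the exact test can reach no adjusted p under 0.05 here unless many lists reach its smallest p, and array weights put most weight on kidney wild-type 2. For the other changes the cause was not tested.

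The single genes whose direction turned were not called; most had values near 0, but kidney Amacr stood at -0.42 and kidney C1qtnf3 at -0.26. With the adipocyte covariate, artery values were -0.0502 for Adamts12, -0.0836 for Amacr, -0.322 for C1qtnf3, 0.0897 for Cdh6, 0.0194 for Drosha, -0.0978 for Prlr, 0.00352 for Zfr and -0.027 for fatty acid oxidation, and -0.038 for the adipocyte list, which is the covariate itself. With array weights they were -0.0827 for artery C1qtnf3, and in kidney -0.0231 for Adamts12, 0.00925 for Amacr, 0.105 for C1qtnf3, 0.12 for Mtmr12, -0.042 for Skp2, -0.0544 for cell cycle, 0.0186 for fatty acid oxidation, -0.0555 for natriuretic peptide signalling and -0.0253 for smooth muscle. With median-of-ratios scaling they were -0.00105 for artery C1qtnf3, -0.0191 for artery Rad1, -0.0322 for kidney Adamts12 and -0.0163 for kidney natriuretic peptide signalling. With quantile normalization they were -0.00752 for artery Rad1, and in kidney -0.11 for Adamts12, -0.00041 for Rai14 and -0.0254 for natriuretic peptide signalling, which was -0.0102 without a filter.

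Leaving out single libraries, artery values ran from -0.0119 to 0.253 for Adamts12, -0.087 to 0.19 for C1qtnf3, -0.299 to 0.181 for Cdh6, -0.149 to 0.0511 for Dnajc21, -0.122 to 0.0333 for Drosha, -0.0706 to 0.222 for Prlr, -0.0921 to 0.155 for Rad1, -0.113 to 0.00315 for Rai14, -0.0385 to 0.301 for Sub1, -1.6 to 0.0586 for erythrocytes, -0.0429 to 0.163 for natriuretic peptide signalling and -0.041 to 0.272 for smooth muscle. Kidney values ran from -0.2 to 0.248 for Adamts12, -0.113 to 0.301 for Agxt2, -0.406 to 0.00488 for C1qtnf3, -0.0311 to 0.336 for Cdh6, -0.0682 to 0.0582 for Mtmr12, -0.00079 to 0.322 for Rad1, -0.046 to 0.145 for Rai14, -0.0717 to 0.328 for Skp2, -0.32 to 0.00495 for Tars1 and -0.00252 to 0.142 for Zfr. For kidney lists they ran from -0.0115 to 0.367 for cell cycle, -0.218 to 0.0056 for endothelium, -0.163 to 0.00651 for fatty acid oxidation, -0.122 to 0.113 for natriuretic peptide signalling and -0.0735 to 0.117 for smooth muscle.

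With the replicate number as a replicate block, 0 genes were called in each tissue (843 unadjusted in artery and 460 in kidney). Npr3 was 0.37 in artery and -0.00413 in kidney, kidney Mtmr12 was 0.0454 and kidney natriuretic peptide signalling was -0.0167. No wild-type kidney carries the number 4, so the block takes deletion 4 out of the kidney estimates. These kidney values equal those without deletion 4. Camera called 15 artery, 9 kidney and 15 tissue-difference lists with the block. Whether the numbers pair the libraries is not clear. Once group means were removed, libraries of the same number correlated at 0.359, -0.356, 0.251 and 0.318 in artery (numbers 1 to 4). In kidney they correlated at 0.1, -0.00909 and 0.271 (numbers 1 to 3). Wild-type arteries 1 and 4 and wild-type kidney 3 were closest to the deletion library of their own number, and the others were not.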

Other observations

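The arteries carried fat, nerve, mesothelial and lymphoid transcripts in amounts that differed between libraries of the same genotype. Mesothelial markers had mean log2 values from -0.106 in wild-type 2 to 3.78 in deletion 2, and the list median was 0.77 higher in deletion arteries without being called. B cell markers stood at 4.03 in wild-type 3 and 3.43 in deletion 2, and T and NK cell markers at 2.68 in wild-type 3 and 0.268 in deletion 1. Wild-type 1 held intestinal transcripts such as Vil1, at 5.91 FPKM against 0.624 or less in the other arteries. The pancreatic gene Prss1 stood at 13.0 FPKM in wild-type 4 and 16.7 in deletion 4, and at 1.11 or less in the others. Adipocyte markers varied less, from 6.82 in wild-type 2 to 7.72 in deletion 2, the library with the highest Npr3 in artery.

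In the kidneys deletion 2 stood apart in its balance of tubule segments. Its mean log2 value was 7.37 for proximal tubule markers and 5.60 for loop of Henle and distal tubule markers. In the other kidneys these ran from 7.95 to 8.26 and from 4.91 to 5.42. Glomerular markers stood at 3.58 in it, against 2.54 to 3.19, and Npr3 at 10.7 FPKM. The library labelled kidney male wild-type 3, with its female pattern of sex-linked genes, differed from the other kidneys in drug-metabolising and transport genes too. The cytochrome P450 gene Cyp2c11 was listed at 0 against 7.94 to 27 FPKM. Akr1b7 stood at 72.3 against 0.0427 or less, and the anion transporter Slc22a7 at 69.8 against 1.3 to 5.32. Whether these differences go with sex was not tested.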
